A study of Mus musculus with 14 samples.

How the data were processed

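The libraries were made from wild-type C57BL/6 embryos. Per the labels, dissected tissue was frozen on dry ice, RNA was extracted with an RNeasy Micro kit, and polyA libraries were prepared with an Illumina or a Kapa kit. The deposited count table, made by the authors, holds raw read counts for 53465 genes in each of the 14 libraries. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.0a, featureCounts 1.6.0, DESeq2 1.20.0 and the GRCm38/mm10 genome. Which step each tool served, and with which settings, is not given in the sources used here. Of the gene IDs, 53274 are in GENCODE M21 and 51335 of those have the same coordinates there (96.4%), while 108 symbols are borne by more than 1 ID. No 2 libraries held identical values. Sequence reads were not analysed here.

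Columns were matched to samples by their names. The 3 second-round AGM columns carry sample numbers without an age, and were matched by the ages that the first-round labels give to the same numbers. That mapping rests on an assumption. Each of these columns correlated most with the first-round library of its number, at r = 0.993 against 0.991 and 0.952 for the one labelled E9.5, 0.995 against 0.983 and 0.969 for E10.5, and 0.994 against 0.966 and 0.941 for E11.5. Calls of the smaller fits were not tested without these libraries, since no AGM age would then have a replicate.

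Comparisons, groups and alternative settings were fixed before the data were examined. They are 4 skin age comparisons, 2 AGM age comparisons, AGM against skin at E9.5 and at E10.5, and the difference between the tissues' changes from E9.5 to E10.5. Counts were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed by filterByExpr by group, library sizes were scaled by TMM, and 7 group means were fitted with glmQLFit and tested with glmQLFTest. P-values were adjusted over all tested genes of a comparison by Benjamini-Hochberg and called under 0.05. This fit used all 14 libraries, 20429 genes and 7 residual degrees of freedom.

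A fit of the 6 AGM libraries was set before the data were examined, as an alternative setting. That fit kept 17613 genes and 3 residual degrees of freedom. A fit of the 10 libraries without second-project skin was added after seeing the data and kept 19945 genes and 3 residual degrees of freedom. It has no skin replicates, so its dispersion comes from the AGM pairs alone. Common dispersion was 0.664 over all 14 libraries (coefficient of variation 81.5%), 0.0146 over the AGM libraries (12.1%) and 0.0147 over the 10 libraries (12.1%). Tissue and sequencing project are confounded, since no project holds both tissues.

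Whether replicate numbers pair samples was tested by correlating the replicate differences of different ages across 19107 genes. Correlations were 0.728 to 0.942 over 6 pairs of skin ages and 0.356 to 0.507 over 3 pairs of AGM ages, so numbers mark a shared project or round. The blocked fit adds that project or round within tissue as a term, coded to sum to 0, and lowers the common dispersion over all 14 libraries to 0.0923 (30.4%).

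Other settings, set before the data were examined, were median-of-ratios size factors, DESeq2 1.42.0 with a Wald test, limma-voom with limma 3.58.1, no low-count filter, the replicate block, leaving globin and mitochondrially encoded genes out, only the compared tissue or ages, each library left out in turn, and glmTreat against a log2 change of 1. Fits without the second-round AGM libraries and the alternatives within the 6-library and 10-library fits were chosen after seeing the data.

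Gene lists, 44 in number with 448 genes of which 445 are in the count table, were written from general knowledge before the data were examined. Each was tested by fry, and its p-values were adjusted by Benjamini-Hochberg over all lists and comparisons together, 396 tests over all 14 libraries and 394 in the smaller fits. Member genes were also adjusted over the list alone. Named genes follow a rule set before the data were examined. It takes the 5 largest positive and 5 largest negative log2 changes among genes with an adjusted p under 0.05, a mean of 5 CPM or more in the higher group, and each library of one group above each of the other. Predicted genes and genes without a symbol were left out. In the 10-library fit that rule was applied over the libraries present. For the difference between tissues, the AGM change minus the skin change had to keep its sign in both AGM rounds. Both rounds were set against the same single skin change, so a large skin change alone can meet that condition. Other named genes are mostly list members, and the result of a member's list is not given in every case. Not every gene that meets the rule is named in the text.

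Where a group had 0 counts, its fold is a floor set by 3 counts over the group. With 1 to 3 counts a ratio with a 95% counting interval, or CPM only, is given. Shares carry 95% Wilson intervals. Library correlations used log2 CPM with a pseudocount of 1 and a mean of 1 CPM or more.

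Simulated counts with 200 changed genes, drawn from each gene's mean share over the libraries and its estimated dispersion, were passed through the same code. For AGM E11.5 against E10.5 the 14-library fit recovered 0% of 2-fold and 0% of 4-fold changes, and the 6-library fit 96% and 100%. For skin E14.5 against E12.5 the 10-library fit recovered 58% of 2-fold and 99% of 4-fold changes, and for AGM against skin at E10.5 it recovered 77% and 100%. Unchanged genes made up 6.67%, 8.19% and 10.2% of the calls in the last 3 cases, above the nominal 5%. Skin counts were simulated with the AGM spread, so the 10-library cases cannot check whether real skin varies like the AGM pairs. Of 10 raised lists fry called 9 in the 14-library fit and 10 in the others, and of 40 unchanged lists 0 in each. Genes were simulated independently, so these list results do not cover lists whose genes vary together.

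Text tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.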

Results

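Gene expression was measured by polyA RNA-seq in wild-type C57BL/6 mouse embryos. Dorsal skin was sampled at E9.5, E10.5, E12.5 and E14.5. The aorta-gonad-mesonephros region (AGM), where the definitive blood stem cells first arise beside the dorsal aorta, was sampled at E9.5, E10.5 and E11.5. At E9.5 the AGM libraries come from the caudal part of the embryo with the para-aortic splanchnopleura, the forerunner of the AGM. Each of the 7 groups has 2 libraries, so 8 libraries are skin and 6 are AGM. Within a tissue, replicate 1 of every age comes from one sequencing project or round and replicate 2 from another. The labels do not say whether the libraries of a group come from separate embryos, so p-values measure only the spread between these samples. The 3 second-round AGM columns carry sample numbers only, and were given the ages that the first-round labels tie to those numbers.

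Total counts in first-project skin were 19929352 at E9.5, 22716613 at E10.5, 24003912 at E12.5 and 22338224 at E14.5. In second-project skin they were 8820803, 14044081, 6770338 and 15440012 at the same ages. The first AGM round held 29534551, 24513201 and 24820391 counts at the labelled ages E9.5, E10.5 and E11.5, and the second 24335839, 25818165 and 21527400. Between 21650 and 26832 genes had a count in a library. Xist, the transcript of the inactive X chromosome of female cells, lay at 0.2 and 0.61 CPM (counts scaled to library size) in the first-round AGM libraries labelled E9.5 and E10.5, and between 256 and 1035 CPM in the others. The Y-linked gene Ddx3y was present in every library, at 28.7 CPM or more, so most libraries hold RNA of both sexes.

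The second-project skin libraries held different RNA from the first-project libraries of the same ages. Spp1, which encodes the secreted matrix protein osteopontin, reached 22229 to 34966 CPM there and 1.19 to 6.45 CPM in the first project. Mmp3, a secreted matrix protease, lay at 3013 to 5471 CPM against 0 to 0.0448 CPM. Mki67, a marker of dividing cells, ran from 3.54 to 19 CPM against 494 to 870 CPM. Haemoglobin genes, which mark the circulating red cells that any embryonic tissue holds, had 1, 0, 1 and 0 counts in total in second-project skin at E9.5, E10.5, E12.5 and E14.5. The first-project shares would have given 22960, 67113, 15743 and 129507 counts at those depths. Across genes, which are not independent replicates, the skin libraries of an age correlated between projects at r = 0.625 to 0.716, while the rounds of an AGM age correlated at 0.993 to 0.995. The age changes of the 2 skin projects were unrelated across 19107 genes (r between -0.0555 and 0.0534 over the 4 skin comparisons). The AGM rounds' age changes correlated at 0.688 and 0.878.

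**Figure D1:**
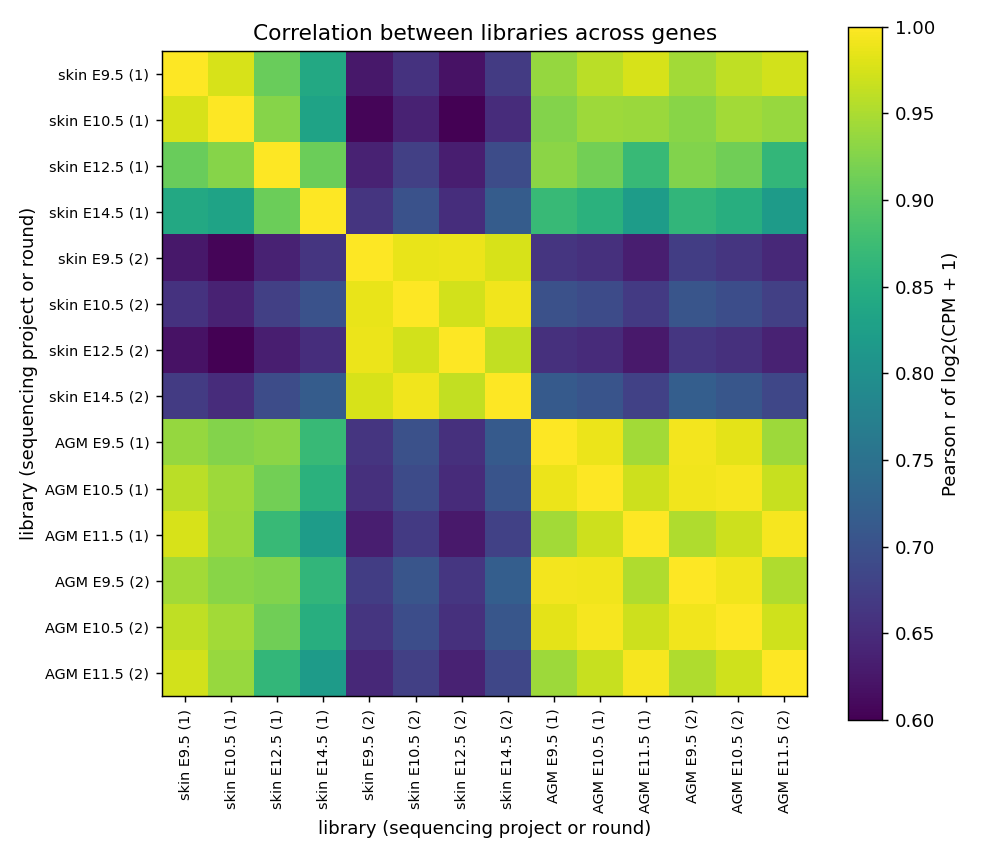
Pearson correlation across genes of log2 CPM between each pair of the 14 libraries, with libraries named on both axes and the colour giving r. The 4 second-project skin libraries correlate with one another at 0.963 to 0.991 and with the AGM libraries at 0.628 to 0.719.

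With those libraries in the shared estimate of spread, edgeR's common dispersion over all 14 libraries was 0.664, a coefficient of variation of 81.5%. The quasi-likelihood test with Benjamini-Hochberg adjustment then called 0 genes in each of the 9 comparisons, with the counts at an unadjusted p under 0.05 given at each comparison. On simulated counts of AGM E11.5 against E10.5, that fit recovered 0% of 2-fold and 0% of 4-fold changes. The genes named here therefore come from 2 smaller fits. List tests are given from the same fits. On those simulated counts fry over all 14 libraries called 9 of 10 raised lists and 0 of 40 unchanged ones. Each gene was drawn independently there, so those values cannot show how fry fares on lists whose genes vary together. The fit of the 6 AGM libraries serves the AGM ages. It was planned before the data were examined as an alternative setting only. Its use as the source of named genes and list calls was chosen after seeing the data. The fit of 10 libraries without second-project skin, chosen after seeing the data, serves the skin ages and the tissue comparisons. In it each skin age is 1 library with no replicate check, assumed to vary like the AGM pairs, so its SEs and adjusted p-values carry the AGM spread. Its called skin changes had the same sign in second-project skin for 47.2% to 52.9% of genes, depending on the comparison, and its tissue differences for 44.6% to 47.8%. Those shares cover only called genes with 10 or more counts in total over the replicate 2 libraries compared. Skin values below are CPM of single first-project libraries, AGM values are CPM of rounds 1 and 2, and ± marks the SE of edgeR's log2 change. With single skin libraries, a change in the tissue that a dissection held cannot be told apart from a change of the skin itself. That limit holds above all skin results below, including neural, cartilage, limb and posterior Hox genes. List tests are fry rotation tests of a shared direction, adjusted over all lists and comparisons. Over all 14 libraries fry called 0 of 396 list tests (14 at an unadjusted p under 0.05), and 32 with the project or round as a block. In the smaller fits it called 159 of 394, and 148 with the AGM round as a block. Leaving out 1 AGM library left between 57 (without the second-round library labelled E10.5) and 105 list calls (without the second-round library labelled E9.5). Each such fit also has fewer residual degrees of freedom, and the weight of the library left out was not separated from that loss. A blocked adjusted p is given for each described list whose call ended with the block.

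The first skin interval, E9.5 to E10.5, asks which genes change as the trunk surface is laid down, before the epidermis stratifies. Genes of developing neurons were higher at E10.5 and genes of simple epithelium lower. Barhl1, a homeobox gene of dorsal spinal cord neurons (ENSMUSG00000026805, GRCm38 chromosome 2, 28907679 to 28916668), rose from 0.251 to 19.4 CPM, a log2 change of 6.24 ± 0.65 (edgeR adjusted p = 0.00193). Gsx1, of neural progenitors, rose by 5.85 ± 0.64 and Robo3, a guidance receptor of commissural axons, by 5.48 ± 0.75. Slc17a6, a vesicular glutamate transporter, went from 0.0502 CPM (1 count) to 5.37 CPM, a ratio of 107 (95% counting interval 19.2 to 4228). Ppp1r1c was at least 36.8-fold higher, against 0 counts at E9.5. On the falling side, Nepn, which encodes nephrocan, was at least 144-fold lower at E10.5 (19.1 to 0 CPM). Ambp, a plasma protein gene of liver and yolk sac, was at least 39.8-fold lower. Gata4, of heart and coelomic mesoderm, changed by -6.35 ± 0.74 (32.7 to 0.396 CPM). Tbx5, of forelimb and heart, went from 19.7 to 0.044 CPM (ratio 448, interval 80.4 to 17694), and Barx1 from 13.4 to 0.044 CPM (ratio 305, interval 54.8 to 12066).

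Of 13 neural tube and neuron genes, 8 rose, 1 fell and 4 did not pass (8 and 1 adjusted over the list alone), and fry gave an upward direction (adjusted p = 0.00844). Dcx, a microtubule protein of young neurons, rose from 29.9 to 349 CPM, and the neurofilament gene Nefm from 71.8 to 553 CPM (2.95 ± 0.17, adjusted p = 3.4e-04). Neural crest and glia genes had 2 of 7 higher, Fabp7 and Ngfr, and 5 not past (2 and 0 adjusted over the list alone; fry adjusted p = 0.00823). Macrophage genes rose in 9 of 12, with 3 not past (10 and 0 adjusted over the list alone; adjusted p = 0.0114). Among them Csf1r, the receptor that macrophages need to survive, went from 0.903 to 7.18 CPM. Simple epithelium fell in 7 of 8 genes, with 1 not past (0 and 7 adjusted over the list alone; adjusted p = 0.0109). Krt8 changed by -2.53 ± 0.21, Krt18 by -2.45 ± 0.19, Cldn6 by -2.27 ± 0.18 and Epcam by -1.94 ± 0.24. Early embryonic timing genes fell in 5 of 9, with 4 not past (0 and 6 adjusted over the list alone; adjusted p = 0.0388, and 0.0959 with the block). The RNA-binding protein Lin28a, which blocks maturation of the let-7 microRNAs, dropped from 366 to 84.6 CPM, Trim71 from 250 to 98.7 CPM and Sall4 from 161 to 67.8 CPM. None of 20 cell cycle genes passed in this fit (none adjusted over the list alone; fry adjusted p = 0.207). Without second-project skin, edgeR called 1282 genes, 925 higher and 357 lower, and 3872 with the AGM round as a block. With every library in the fit edgeR called 0 with or without the block (80 at an unadjusted p under 0.05 without it), limma-voom 0, and DESeq2 2, Ckm and Pla2g4f, named after their values were seen.

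Between E10.5 and E12.5, genes of keratinocytes, dermis, muscle and cartilage rose in the first-project skin libraries while neural and early-timing genes fell. Whether the skin itself or other tissue in the dissection changed was not tested. Hoxd12, a posterior homeobox gene (ENSMUSG00000001823, GRCm38 chromosome 2, 74675013 to 74677705), was at least 656-fold higher (0 to 86.7 CPM). Hoxd11 and Hoxa13, also posterior and distal-limb Hox genes, were at least 440-fold and 438-fold higher. Gdf5, a growth factor of forming joints, was at least 247-fold higher, and the potassium channel subunit gene Kcne4 at least 206-fold. Atoh1, of dorsal neural progenitors, was at least 142-fold lower (17.8 to 0 CPM). Lin28a fell by 7.03 ± 0.49 on the log2 scale (84.6 to 0.667 CPM, adjusted p = 4.9e-05). Olig3, of dorsal neural progenitors, changed by -6.65 ± 0.37, the cell surface gene Igdcc3 by -6.40 ± 0.33 (633 to 7.75 CPM), and Wfikkn1 by -6.00 ± 0.43.

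Basal keratinocyte genes rose in 8 of 10, with 2 not past (8 and 0 adjusted over the list alone; fry adjusted p = 0.00252). Krt5 went from 3.52 to 93.7 CPM and its partner Krt14 from 0.484 to 34.3 CPM (6.08 ± 0.36). All 16 extracellular matrix genes rose (16 and 0 adjusted over the list alone; adjusted p = 0.0128), among them Ogn (6.58 ± 0.33) and elastin, Eln (4.48 ± 0.74). Dermal fibroblast genes rose in 10 of 13, with 1 lower and 2 not past (10 and 1 adjusted over the list alone; adjusted p = 0.00844). Col1a1, of fibrillar collagen, went from 118 to 2363 CPM and Postn from 28.4 to 427 CPM. Skeletal muscle rose in 14 of 15 genes, with 1 not past (14 and 0 adjusted over the list alone; adjusted p = 0.022), including Myod1 (4.55 ± 0.27) and Myh8 (5.66 ± 0.34). All 7 cartilage genes rose (7 and 0 adjusted over the list alone; adjusted p = 0.0112), with Acan at 5.82 ± 0.39 and Col9a1 at 2.36 ± 0.18. All 12 macrophage genes rose (12 and 0 adjusted over the list alone; adjusted p = 0.0057), F13a1 from 3.21 to 35.7 CPM.

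Limb bud genes rose in 4 of 4 (4 and 0 adjusted over the list alone; adjusted p = 0.0273, and 0.0702 with the block), Tbx5 from 0.044 to 179 CPM (ratio 4072, interval 731 to 160840). Hox genes of paralogue groups 10 to 13 rose in 7 of 10, with 3 not past (8 and 0 adjusted over the list alone; adjusted p = 0.0175). In contrast, 13 of 15 Hox genes of groups 1 to 5 fell, 1 rose and 1 did not pass (1 and 14 adjusted over the list alone; adjusted p = 0.00823), Hoxb1 by -5.34 ± 0.37 and Hoxd4 by -3.33 ± 0.24. Neural tube and neuron genes fell in 11 of 13, with 2 not past (0 and 11 adjusted over the list alone; adjusted p = 0.00567). Pax6 went from 111 to 3.29 CPM, Sox1 changed by -4.82 ± 0.22 and Neurog2 by -4.77 ± 0.56. Early timing genes fell in 8 of 9, with 1 not past (0 and 8 adjusted over the list alone; adjusted p = 0.00823), with Sall4 at -4.81 ± 0.30 and Trim71 at -3.67 ± 0.20. Cell cycle genes fell in 19 of 20, with 1 not past (0 and 19 adjusted over the list alone; adjusted p = 0.00567). Their steps were small, as for Mcm7 (-1.12 ± 0.13) and Pcna (-1.08 ± 0.16). Imprinted growth genes rose in 7 of 10, with 3 not past (8 and 0 adjusted over the list alone; adjusted p = 0.00567), Igf2 by 2.94 ± 0.37 and Cdkn1c, an inhibitor of the cell cycle, by 1.43 ± 0.12. In this interval edgeR called 6003 genes, 3462 higher and 2541 lower, without second-project skin, and 9568 with the round as a block. Fitting all 14 libraries together gave 0 edgeR calls (256 at an unadjusted p under 0.05), limma-voom 0, DESeq2 7, and edgeR with the replicate block 2, which were Pax6 (-5.11) and Zbtb16 (-3.97), named after their values were seen.

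From E12.5 to E14.5 the differentiation genes of the epidermis rose. Part of the rise came earlier, since edgeR's median log2 change from E10.5 to E12.5 was 0.54 for suprabasal and cornified keratinocytes and 3.57 for periderm. Krt77, a keratin of suprabasal layers (ENSMUSG00000067594, GRCm38 chromosome 15, 101858732 to 101869705), went from 0.0833 to 455 CPM (ratio 5459, interval 1511 to 45079). The desmosomal cadherin Dsc1 was at least 862-fold higher (0 to 108 CPM), the mucin gene Muc15 at least 214-fold, and Cyp4f39, which makes lipids of the skin barrier, at least 195-fold. Krtdap, of differentiating keratinocytes, went from 0.0417 to 222 CPM (ratio 5335, interval 958 to 210730). Several neuronal regulators fell to 0 counts. Prdm12, of sensory neurons, was at least 128-fold lower, Ppp1r17 at least 95.8-fold, Neurod1 at least 78.7-fold and Otp at least 69.1-fold. Lhx9, of limb, gonad and neurons, went from 93.6 to 0.0448 CPM (ratio 2091, interval 375 to 82593).

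All 13 suprabasal and cornified keratinocyte genes rose (13 and 0 adjusted over the list alone; fry adjusted p = 9.5e-04). Calm4, a calcium-binding protein of keratinocytes, was at least 133-fold higher. All 10 basal keratinocyte genes rose (10 and 0 adjusted over the list alone; adjusted p = 0.00154), Krt5 from 93.7 to 1722 CPM and Krt15 by 4.26 ± 0.23. All 8 periderm genes rose (8 and 0 adjusted over the list alone; adjusted p = 0.00156). Krt4 went from 0.125 to 271 CPM (ratio 2167, interval 742 to 10508), Krt17 changed by 4.11 ± 0.31 and Sfn by 4.12 ± 0.21. All 8 simple epithelium genes rose (8 and 0 adjusted over the list alone; adjusted p = 0.00497), Krt19 by 5.60 ± 0.25 and Cdh1 by 4.34 ± 0.18. Hair placode genes rose in 8 of 11, with 2 lower and 1 not past (8 and 2 adjusted over the list alone; adjusted p = 0.00759). The placode receptor Edar changed by 3.25 ± 0.36.

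In the dermis, 11 of 13 fibroblast genes rose, 1 fell and 1 did not pass (11 and 1 adjusted over the list alone; adjusted p = 0.0119). Dpt went from 1.92 to 176 CPM, Dcn from 113 to 938 CPM and Postn from 427 to 1964 CPM. Melanoblast genes rose in 5 of 7, with 1 lower and 1 not past (5 and 1 adjusted over the list alone; adjusted p = 0.00148). The pigment enzymes Dct and Tyr changed by 3.08 ± 0.32 and 3.64 ± 0.74, and Pmel by 3.45 ± 0.48. All 5 mast cell genes rose (5 and 0 adjusted over the list alone; adjusted p = 0.00156), with Cma1 at 7.21 ± 0.33, Cpa3 at 4.97 ± 0.24 and Tpsb2 from 0.125 to 49.8 CPM. Adipogenic genes rose in 3 of 3 (3 and 0 adjusted over the list alone; adjusted p = 0.00442), Cebpa by 4.09 ± 0.27 and Pparg by 3.66 ± 0.43. Macrophage genes rose in 7 of 12, with 5 not past (8 and 0 adjusted over the list alone; adjusted p = 0.0181).

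Cartilage, posterior Hox, neural and somite genes fell over the same interval, while skeletal muscle had 8 of 15 genes higher, 1 lower and 6 not past (9 and 1 adjusted over the list alone; fry adjusted p = 0.128). All 7 cartilage genes fell (0 and 7 adjusted over the list alone; adjusted p = 0.00823), Col2a1 from 1281 to 51.7 CPM and Col9a1 from 288 to 6.54 CPM. Hox groups 10 to 13 fell in 7 of 10 genes, with 1 higher and 2 not past (1 and 7 adjusted over the list alone; adjusted p = 0.0273), Hoxd13 by -10.22 ± 0.70 and Hoxa13 by -7.60 ± 0.35. Neural tube and neuron genes fell in 12 of 13, with 1 not past (0 and 13 adjusted over the list alone; adjusted p = 0.00353), with Elavl3 at -5.76 ± 0.24, Nefm at -5.23 ± 0.19 and Tubb3 at -5.01 ± 0.21. Somite and dermomyotome genes fell in 7 of 10, with 3 not past (0 and 8 adjusted over the list alone; adjusted p = 0.0075). Foxc2 changed by -4.69 ± 0.28, and Uncx went from 13.1 to 0.134 CPM (ratio 97.4, interval 33.3 to 472). Sympathoadrenal genes fell in 7 of 9, with 2 not past (1 and 7 adjusted over the list alone; adjusted p = 0.0108), Th from 12.0 to 0.0895 CPM. Retinoic acid pathway genes fell in 3 of 8, with 5 not past (0 and 5 adjusted over the list alone; adjusted p = 0.00442). The synthesis enzyme Aldh1a2 changed by -5.33 ± 0.19 and the binding protein Crabp2 by -2.61 ± 0.30.

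All 14 hypoxia and glycolysis genes rose (14 and 0 adjusted over the list alone; adjusted p = 0.0075), Ndrg1 by 3.42 ± 0.20 and the glucose transporter Slc2a1 by 3.02 ± 0.21. Immediate early and heat shock genes rose in 8 of 10, with 2 not past (8 and 0 adjusted over the list alone; adjusted p = 0.0128). Fos went from 4 to 70.1 CPM and Hspa1a from 0.583 to 65.9 CPM in the same pair of libraries. Adult globins rose as well, Hbb-bs from 39.1 to 3076 CPM and Hbb-bt from 59.2 to 1350 CPM, while their list test did not pass (8 higher, 5 not past, 10 and 0 adjusted over the list alone; adjusted p = 0.0787). Notch pathway genes rose in 5 of 8, with 2 lower and 1 not past (5 and 2 adjusted over the list alone; adjusted p = 0.0483), with Jag2 at 2.21 ± 0.20 and Notch1 at 2.19 ± 0.24. In the 10-library fit edgeR called 5488 genes, 2846 higher and 2642 lower, and 9023 with the round as a block. In the 14-library fit it called 0 (444 at an unadjusted p under 0.05), limma-voom 0, DESeq2 12, and edgeR with the replicate block 10. On simulated counts of this comparison the 10-library fit recovered 58% of 2-fold and 99% of 4-fold changes, and 8.19% of its calls were unchanged genes. Those counts gave skin the spread of the AGM pairs, so they cannot show how calls fare on real skin.

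**Figure D2:**
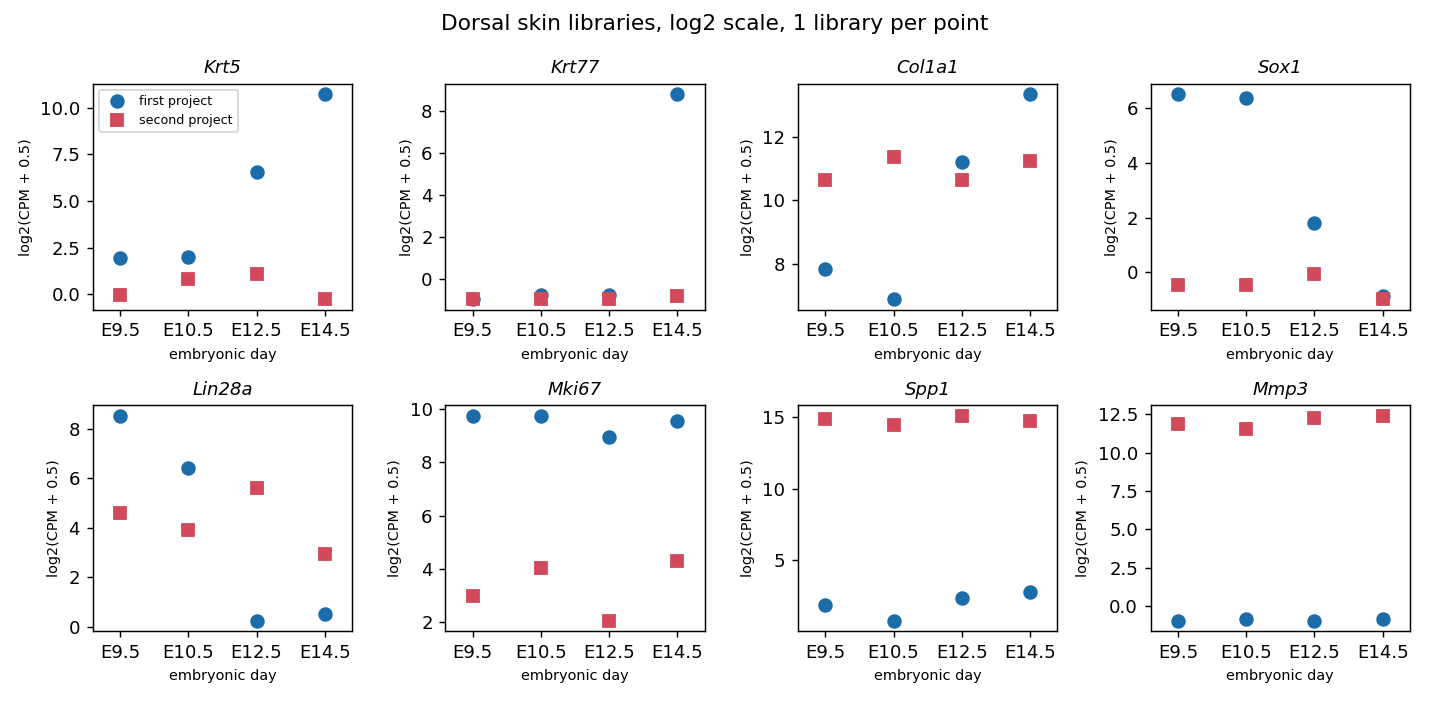
CPM of 8 genes on a log axis against embryonic day in dorsal skin, 1 point per library, with the projects drawn separately. Krt5 climbs from 3.36 to 1722 CPM and Lin28a drops from 366 to 0.94 CPM in first-project skin between E9.5 and E14.5, while Mmp3 lies between 3013 and 5471 CPM in second-project skin.

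Over the whole series, E14.5 against E9.5, first-project skin gained keratins, collagens and resident immune cell genes and lost neural genes. Most cell cycle genes also fell, while Mki67 went from 870 CPM at E9.5 to 494 at E12.5 and 764 at E14.5. Krt77 was at least 3020-fold higher, Cpa3, a mast cell protease (ENSMUSG00000001865, GRCm38 chromosome 3, 20215620 to 20242181), at least 1220-fold, Krt17 at least 1020-fold, S100a14 at least 962-fold and the desmosomal Dsg1a at least 850-fold. Olig3 was at least 198-fold lower, Wnt1, of the dorsal neural tube, at least 97.8-fold, and Prdm12 at least 95.2-fold. Krt5 changed by 9.08 ± 0.46 and Krt14 by 9.53 ± 0.35. Col1a1 went from 231 to 10467 CPM (5.59 ± 0.51) and Ogn changed by 9.66 ± 0.42. All 12 macrophage genes rose (12 and 0 adjusted over the list alone; fry adjusted p = 0.0026), F13a1 from 0.251 to 90.1 CPM. Skeletal muscle rose in 14 of 15 genes, with 1 not past (14 and 0 adjusted over the list alone; adjusted p = 0.011). Myh8 went from 0.602 to 403 CPM, and Myod1 changed by 5.97 ± 0.35.

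All 9 early timing genes fell across the series (0 and 9 adjusted over the list alone; fry adjusted p = 0.00442), Sall4 by -8.90 ± 0.40, Lin28a by -8.52 ± 0.48, Lin28b by -6.34 ± 0.33 and Trim71 by -5.83 ± 0.22 (adjusted p = 1.9e-06). Cell cycle genes fell in 17 of 20, with 3 not past (0 and 17 adjusted over the list alone; adjusted p = 0.00536), with Mcm7 at -1.88 ± 0.13, Mcm5 at -1.44 ± 0.19 and Plk1 at -1.24 ± 0.16. Hox groups 1 to 5 fell in 13 of 15 genes, with 2 not past (0 and 13 adjusted over the list alone; adjusted p = 0.00823), with Hoxb1 at -6.60 ± 0.41 and Hoxd3 at -3.87 ± 0.26. Neural tube and neuron genes fell in 11 of 13 and rose in 2 (2 and 11 adjusted over the list alone; adjusted p = 0.00337), Nkx6-1 from 92.8 to 0.269 CPM. Imprinted growth genes rose in 6 of 10, with 2 lower and 2 not past (7 and 2 adjusted over the list alone; adjusted p = 0.00567), Dlk1 by 2.94 ± 0.18 and Cdkn1c by 2.58 ± 0.13. Wnt pathway genes rose in 5 of 8, with 3 not past (6 and 0 adjusted over the list alone; adjusted p = 0.0129), Wif1 by 4.86 ± 0.36 and Rnf43 by 4.26 ± 0.37. Retinoic acid pathway genes fell in 5 of 8, with 1 higher and 2 not past (1 and 5 adjusted over the list alone; adjusted p = 0.00353), Aldh1a2 by -5.85 ± 0.19 and Crabp2 by -4.32 ± 0.32. Neural crest and glia rose in 3 of 7, with 2 lower and 2 not past (3 and 3 adjusted over the list alone). Their fry direction was up (adjusted p = 0.0251) while the list's median log2 change was -0.31. The neuregulin receptor gene Erbb3 changed by 1.84 ± 0.15, against -0.99 ± 0.16 for Sox10. Smooth muscle and pericyte genes rose in 6 of 7, with 1 not past (6 and 0 adjusted over the list alone; adjusted p = 0.0235), Rgs5 by 3.24 ± 0.26. Endothelial genes rose in 5 of 11, with 6 not past (5 and 0 adjusted over the list alone; adjusted p = 0.14), the adhesion gene Pecam1 by 1.97 ± 0.21. Across these ages edgeR called 9294 genes, 5162 higher and 4132 lower, without second-project skin. Over all 14 libraries it called 0 (814 at an unadjusted p under 0.05), limma-voom 0, DESeq2 46, and edgeR with the replicate block 34.

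Between the AGM libraries labelled E9.5 and E10.5, most macrophage genes fell, and some genes of the neural tube and of early timing rose. Olig2, of motor neuron progenitors (ENSMUSG00000039830, GRCm38 chromosome 16, 91225550 to 91228677), went from 0.237 and 0.288 CPM to 7.02 and 6.16 CPM, a change of 4.69 ± 0.24 (edgeR adjusted p = 0.00102). The neural transcription factors Rfx4, Neurog2 and Neurod4 changed by 3.07 ± 0.33, 2.85 ± 0.46 and 2.69 ± 0.38, and Mir124-2hg, the host transcript of a neuronal microRNA, by 2.95 ± 0.52. Kctd14 fell from 28.2 and 12.7 CPM to 0.857 and 0.581 CPM (-4.77 ± 0.47). Clca3a1 changed by -3.51 ± 0.37, Gdf10 by -2.63 ± 0.26, Nr1h5 by -2.57 ± 0.27 and Ogn by -2.51 ± 0.35.

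Macrophage genes fell in 11 of 12, with 1 not past (0 and 12 adjusted over the list alone; fry adjusted p = 0.00802). The complement gene C1qa changed by -1.74 ± 0.25, C1qb by -1.45 ± 0.21, Lyz2 by -1.66 ± 0.23 and Adgre1, the F4/80 antigen, by -1.80 ± 0.30. Neural tube and neuron genes rose in 5 of 13, with 1 lower and 7 not past (7 and 1 adjusted over the list alone; adjusted p = 0.0177, and 0.0529 with the block). Early timing genes rose in 3 of 9, with 6 not past (5 and 0 adjusted over the list alone; adjusted p = 0.0329, and 0.0888 with the block), Lin28a from 23 and 40.8 to 121 and 129 CPM, Lin28b by 1.36 ± 0.18 and Trim71 by 1.03 ± 0.13. Sox2 rose by 1.15 ± 0.13, Hoxb9 by 0.96 ± 0.10, and the Notch ligands Dll1 and Dll3 by 0.97 ± 0.17 and 1.11 ± 0.17. Results of the lists that hold these genes are not given for this comparison. Of 18 haematopoietic stem and progenitor genes only Gata2 changed (-1.44 ± 0.27), with 17 not past (0 and 1 adjusted over the list alone; adjusted p = 0.426). Extracellular matrix genes fell in 7 of 16, with 9 not past (0 and 11 adjusted over the list alone; adjusted p = 0.0753), among them Col12a1 (-1.72 ± 0.21) and Eln (-2.43 ± 0.47). The 6-library fit called 457 genes, 154 higher and 303 lower, and 4237 (2131 higher and 2106 lower) with the round as a block. The count fell to 1, Olig2, without the second-round library labelled E10.5, to 24 without the first-round library labelled E9.5 and to 104 without the first-round library labelled E10.5. With all 14 libraries fitted, edgeR called 0 with or without the block (27 at an unadjusted p under 0.05 without it), limma-voom 0, and DESeq2 5, Ccl11, Ms4a7, Ifit3b, Gm9159 and Gm7940, named after their values were seen.

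The libraries labelled E11.5 held far more tailbud RNA than those labelled E10.5, and less RNA of the urogenital ridge. Wnt3a, the Wnt ligand of the tailbud (ENSMUSG00000009900, GRCm38 chromosome 11, 59248033 to 59290752), was at least 188-fold higher (0 in both against 13.4 and 9.15 CPM). The neural tube genes Prdm13 and Wnt1 were at least 145-fold and 125-fold higher, and Cer1, a secreted antagonist of Nodal and BMP, at least 99.1-fold. Cdx4, of the tailbud, had 1 count in the libraries labelled E10.5 and 51.9 and 29.2 CPM in those labelled E11.5 (ratio 2040, interval 366 to 80578). Dbh, which makes noradrenaline, fell from 61.0 and 42.2 CPM to 0.201 and 0.186 CPM (-7.93 ± 0.32, adjusted p = 1.1e-05). Agtr2, an angiotensin receptor gene, was lower with a ratio of 1007 (interval 181 to 39780). Nr5a1, the regulator of gonad and adrenal fate, was lower with a ratio of 197 (interval 54.6 to 1629). Tlx2, of enteric neurons, and Cx3cr1, of macrophages, were lower with ratios of 168 (interval 57.6 to 816) and 165 (interval 56.3 to 798).

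All 13 presomitic mesoderm and tailbud genes rose (13 and 0 adjusted over the list alone; fry adjusted p = 0.0128). Cdx2 changed by 5.34 ± 0.49, and Msgn1 was at least 87.8-fold higher. Early timing genes rose in 6 of 9, with 3 not past (6 and 1 adjusted over the list alone; adjusted p = 0.0288, and 0.0752 with the block), with Lin28a at 571 and 496 CPM (2.18 ± 0.23) and Sall4 at 1.54 ± 0.17. Cell cycle genes rose in 11 of 20, with 9 not past (14 and 0 adjusted over the list alone; adjusted p = 0.0175, and 0.0542 with the block). Simple epithelium rose in 7 of 8 genes, with 1 not past (8 and 0 adjusted over the list alone; adjusted p = 0.00567), Krt8 by 2.16 ± 0.13 and Krt18 by 1.78 ± 0.12. Endoderm and yolk sac genes rose in 7 of 8, with 1 not past (8 and 0 adjusted over the list alone; adjusted p = 0.0269), and differed between rounds, with Afp at 15.6 and 106 CPM and Ttr at 3.87 and 23.6 CPM. Hypoxia and glycolysis genes rose in 10 of 14, with 4 not past (11 and 1 adjusted over the list alone; adjusted p = 0.0161), Slc2a1 by 2.57 ± 0.15 and Ldha by 1.23 ± 0.10. The neural tube list split, with 5 higher, 6 lower and 2 not past (5 and 8 adjusted over the list alone; adjusted p = 0.182). The progenitor genes Pax6 (5.20 ± 0.24) and Sox1 (5.10 ± 0.18) were higher, and the neuronal genes Nefm (-3.11 ± 0.12) and Dcx (-2.62 ± 0.27) lower.

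All 12 macrophage genes fell (0 and 12 adjusted over the list alone; adjusted p = 0.00366), F13a1 by -4.24 ± 0.27 and Mrc1 by -3.41 ± 0.27. Mesonephros and intermediate mesoderm fell in 8 of 12 genes, with 1 higher and 3 not past (1 and 8 adjusted over the list alone; adjusted p = 0.0206). Wt1, of the urogenital ridge, went from 86.4 and 78.0 to 8.86 and 8.87 CPM, Wnt9b changed by -2.56 ± 0.22 and Emx2 by -2.31 ± 0.16. Sympathoadrenal genes fell in 6 of 9, with 3 not past (0 and 6 adjusted over the list alone; adjusted p = 0.00946), with Th at -3.28 ± 0.23 and Chgb at -2.64 ± 0.18. Skeletal muscle fell in 14 of 15 genes, with 1 not past (0 and 14 adjusted over the list alone; adjusted p = 0.0195), Myh3 by -3.73 ± 0.35 and Myog by -3.26 ± 0.29. Cartilage fell in 5 of 6, with 1 not past (0 and 5 adjusted over the list alone; adjusted p = 0.017), Col2a1 by -1.50 ± 0.19. Hox groups 10 to 13 fell in 8 of 9, with 1 not past (0 and 8 adjusted over the list alone; adjusted p = 0.0483, and 0.0728 with the block), Hoxd13 by -2.84 ± 0.41, while the anterior Hoxb1 rose by 2.56 ± 0.19. Immediate early genes fell in 7 of 10, with 3 not past (0 and 7 adjusted over the list alone; adjusted p = 0.0205), Fos by -3.01 ± 0.17 and Egr1 by -2.90 ± 0.16. Imprinted growth genes fell in 6 of 10, with 4 not past (0 and 7 adjusted over the list alone; adjusted p = 0.0073), Cdkn1c by -1.96 ± 0.09. Haematopoietic stem and progenitor genes showed no shared direction, with 3 higher, 6 lower and 9 not past (3 and 6 adjusted over the list alone; adjusted p = 0.309). Mecom changed by -1.40 ± 0.10, Myb by -1.09 ± 0.18 and Adgrg1 by 0.93 ± 0.23.

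In this comparison the 6-library fit called 4791 genes, 2075 higher and 2716 lower, and 8491 with the round as a block. The count was 2860 and 2794 without the first-round and second-round library labelled E10.5, and 3097 and 3156 without those labelled E11.5. Over all 14 libraries edgeR called 0 (485 at an unadjusted p under 0.05), limma-voom 0, DESeq2 74, and edgeR with the replicate block 50. On simulated counts of this comparison the 6-library fit recovered 96% of 2-fold and 100% of 4-fold changes, and 6.67% of its calls were unchanged genes.

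**Figure D3:**
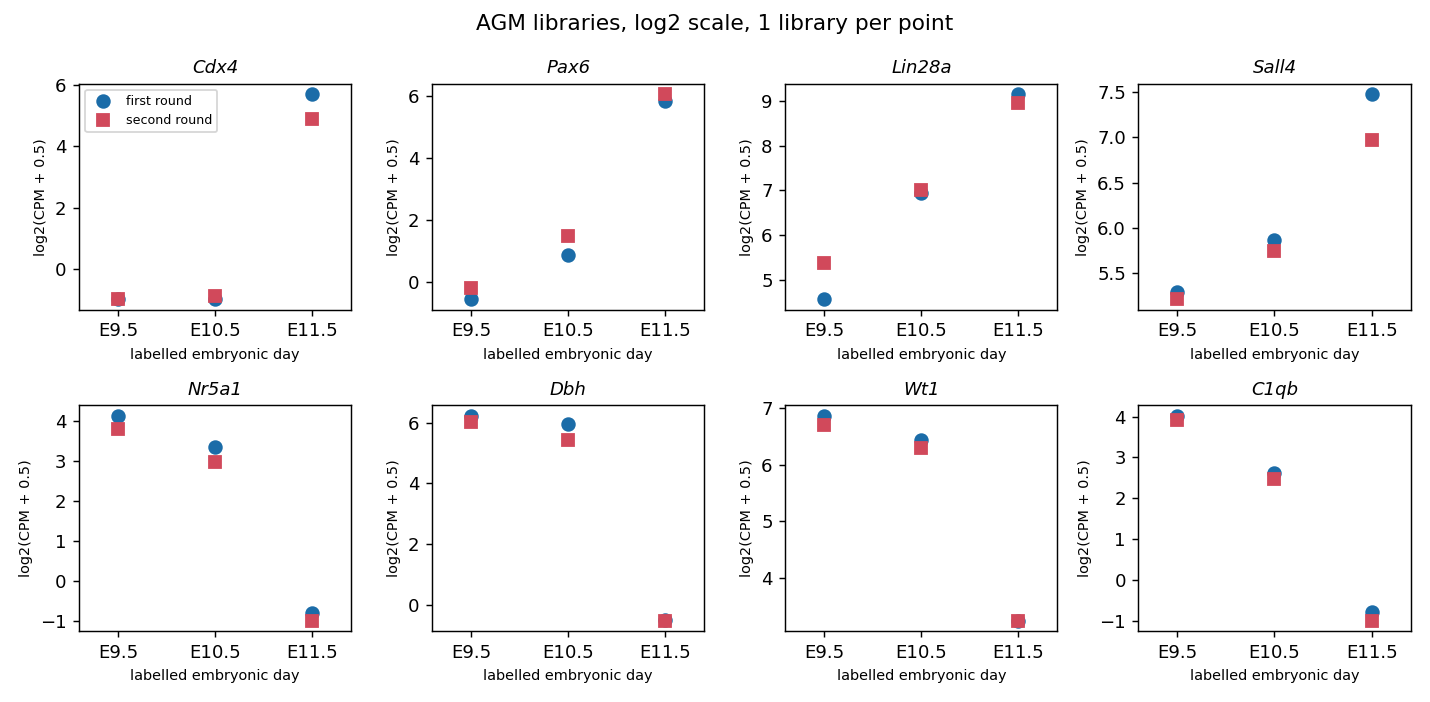
CPM of 8 genes on a log axis against the labelled embryonic day in the AGM, 1 point per library. Cdx4, Pax6, Lin28a and Sall4 are highest and Nr5a1, Dbh, Wt1 and C1qb lowest in both libraries labelled E11.5.

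The embryonic beta-type globins give a separate but coarse reading of age, since primitive red cells switch from Hbb-bh1 to Hbb-y as they mature. In first-project skin the Hbb-bh1 share of both transcripts was 34.8% at E9.5 (95% Wilson interval 34.3 to 35.4), 35.0% at E10.5, 5.18% at E12.5 and 1.18% at E14.5 (1.08 to 1.29). In the AGM libraries labelled E9.5, E10.5 and E11.5 it was 25.8% (25.7 to 26.0), 32.4% (32.2 to 32.6) and 42.5% (42.3 to 42.8) in the first round. In the second round it was 33.8% (33.5 to 34.0), 37.3% (37.1 to 37.5) and 45.8% (45.6 to 46.0). The share did not fall between E9.5 and E10.5 in skin, and no skin library covers E11.5. AGM libraries labelled E9.5 also differed between rounds (25.8% and 33.8%), while those labelled E11.5 lay above every skin library. Intervals and fold floors cover counting error only, and a floor is 3 counts over the group.

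**Figure D4:**
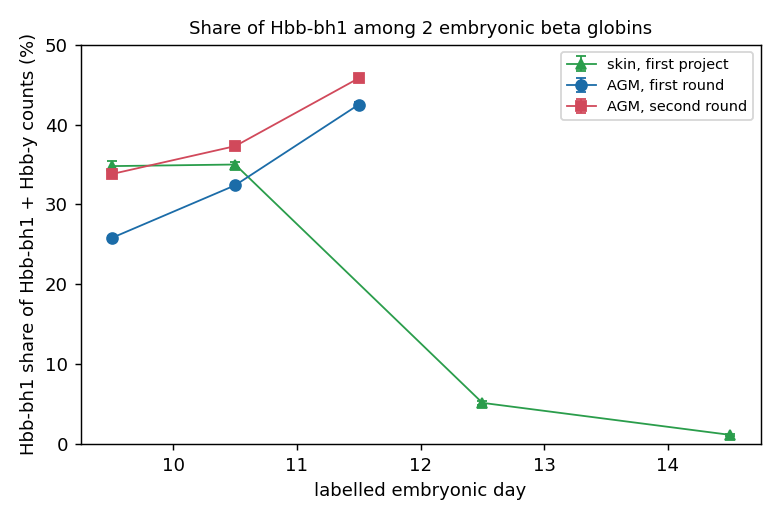
Share of Hbb-bh1 in the sum of Hbb-bh1 and Hbb-y counts, in percent, against the labelled embryonic day, 1 point per library with 95% Wilson intervals. The share drops from 35.0% to 1.18% between E10.5 and E14.5 in first-project skin, and is higher at each later labelled age in both AGM rounds.

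At E9.5 the AGM libraries and first-project skin differed in position along the body and in organ content. Posterior Hox genes and genes of mesonephros, macrophages and sympathoadrenal cells were higher in the AGM, and neural tube genes higher in skin. Hoxd12 (17.7 and 16.1 CPM) and Hoxc11 (12.3 and 11.8 CPM) were at least 112-fold and 80-fold higher in the AGM, against 0 counts in skin. Nr5a1 (ENSMUSG00000026751, GRCm38 chromosome 2, 38692656 to 38714542) reached 17.0 and 13.4 CPM, at least 100-fold higher. Clca3a1 was at least 52.1-fold higher and the macrophage protease gene Ctss at least 51.6-fold. In the fit of all 14 libraries Clca3a1 and Ctss took the opposite sign (-0.14 and -3.61), with 14.2 and 155 CPM in second-project skin at E9.5. Sox1, of neural progenitors (ENSMUSG00000096014, GRCm38 chromosome 8, 12395295 to 12400126), was lower in the AGM by -9.92 ± 0.24 (0.0677 and 0.123 against 91.8 CPM, edgeR adjusted p = 1.6e-06). Prdm13 was at least 297-fold lower, Wnt1 at least 236-fold and Prl8a2, a prolactin-family gene, at least 93.7-fold. Msx3, of the dorsal neural tube, had 1 count in the AGM against 44.6 CPM (ratio 2400, interval 431 to 94808).

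Hox groups 10 to 13 were higher in 9 of 10 genes, with 1 not past (9 and 0 adjusted over the list alone; fry adjusted p = 0.0218), Hoxc10 by 7.90 ± 0.63. Hox groups 1 to 5 were lower in 10 of 15, with 5 not past (0 and 12 adjusted over the list alone; adjusted p = 0.0166, and 0.0501 with the block), Hoxb1 by -3.34 ± 0.22. Mesonephros and intermediate mesoderm was higher in 10 of 12 genes, with 1 lower and 1 not past (10 and 1 adjusted over the list alone; adjusted p = 0.0161), including Wt1 (117 and 104 against 12.1 CPM), Wnt9b (3.75 ± 0.33) and Emx2 (2.96 ± 0.23). Sympathoadrenal genes were higher in 6 of 9, with 3 not past (7 and 0 adjusted over the list alone; adjusted p = 0.0161), with Dbh at 7.05 ± 0.40, Chgb at 2.95 ± 0.23 and Th at 2.91 ± 0.29. All 12 macrophage genes were higher (12 and 0 adjusted over the list alone; adjusted p = 0.00366), F13a1 by 6.12 ± 0.37. Smooth muscle and pericyte genes were higher in 6 of 7, with 1 not past (7 and 0 adjusted over the list alone; adjusted p = 0.018), with Rgs5 at 3.63 ± 0.25, Myh11 at 3.54 ± 0.58 and Cnn1 at 2.26 ± 0.34. Neural tube and neuron genes were lower in 8 of 13, with 3 higher and 2 not past (3 and 8 adjusted over the list alone; adjusted p = 0.00664), with Pax6 at -8.84 ± 0.31, Olig2 at -7.66 ± 0.23 and Neurog2 at -5.32 ± 0.45. Early timing genes were lower in 8 of 9 and higher in 1 (1 and 8 adjusted over the list alone; adjusted p = 0.00802), with Lin28a at -3.58 ± 0.26, Lin28b at -2.69 ± 0.21, Trim71 at -2.66 ± 0.14 and Sall4 at -2.15 ± 0.19.

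Blood genes leaned to the AGM without a list test past the threshold. The 3 embryonic globins were higher (3 and 0 adjusted over the list alone; adjusted p = 0.0545), Hbb-bh1 by 2.33 ± 0.28 and Hba-x by 2.49 ± 0.43. Haematopoietic stem and progenitor genes were higher in 10 of 18, with 2 lower and 6 not past (12 and 2 adjusted over the list alone; adjusted p = 0.0604), Gata2 by 2.28 ± 0.38 and Itga2b by 2.21 ± 0.45. Immediate early genes were higher in 9 of 10, with 1 not past (9 and 0 adjusted over the list alone; adjusted p = 0.0128), with Fos at 159 and 152 against 1.10 CPM and Egr1 at 4.54 ± 0.25. Presomitic and tailbud genes were lower in 7 of 13, with 1 higher and 5 not past (1 and 7 adjusted over the list alone; adjusted p = 0.0292), among them Cdx1 (-4.62 ± 0.40) and Dll1 (-2.31 ± 0.18). The test without second-project skin called 6759 genes, 3586 higher and 3173 lower, and 10234 with the round as a block. Fitting all 14 libraries together gave 0 edgeR calls (950 at an unadjusted p under 0.05), limma-voom 0, DESeq2 308, and edgeR with the replicate block 4321, 2680 higher and 1641 lower. Each tissue has its own sequencing projects, so tissue and project cannot be told apart. Several abundant genes were far lower in first-project skin than in the AGM at every age, for a reason not tested. Rps27 lay at 2.04 to 3.16 against 251.6 to 323.9 CPM, and Actg1 at 4.04 to 9.11 against 619 to 865 CPM. Rpl17 lay at 4.37 to 6.54 against 267 to 447 CPM, and Rps27a at 5.73 to 17.1 against 346 to 560 CPM. Others overlapped, as Rpl4 at 1230 to 1912 against 1407 to 2239 CPM and Rps3 at 652 to 1078 against 794 to 1051 CPM. Such differences may lie within the calls of both tissue comparisons. The Hbb-bh1 share leaves the AGM ages in doubt, so age is not separated from tissue here, which includes the early timing, tailbud, macrophage and urogenital genes.

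At E10.5 the AGM again stood apart by posterior Hox, coelomic and urogenital genes, and skin by neural genes. Tcf21, of visceral mesoderm (ENSMUSG00000045680, GRCm38 chromosome 10, 22817281 to 22820174), was at least 104-fold higher in the AGM (14 and 13.5 against 0 CPM). Hoxd11, Hoxc11 and Hoxd12 were at least 73.4-fold, 42-fold and 40-fold higher. Fosb, an immediate early gene, changed by 8.66 ± 0.55 (110 and 70.3 against 0.22 CPM, edgeR adjusted p = 2.1e-05). The neural genes Prdm13, Wnt1, Atoh1 and Otp were at least 550-fold, 414-fold, 298-fold and 285-fold lower, against 0 counts in the AGM. Msx3 had 1 count there against 90.2 CPM in skin (ratio 4538, interval 814 to 179230).

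All 13 neural tube and neuron genes were lower in the AGM (0 and 13 adjusted over the list alone; fry adjusted p = 0.0026), Sox1 by -5.86 ± 0.18, Pax6 by -5.93 ± 0.25 and Elavl3 by -3.48 ± 0.14. All 15 Hox genes of groups 1 to 5 were lower (0 and 15 adjusted over the list alone; adjusted p = 0.0135), with Hoxb4 at -1.61 ± 0.13. Hox groups 10 to 13 were higher in 9 of 10, with 1 not past (9 and 1 adjusted over the list alone; adjusted p = 0.0232, and 0.0503 with the block), among them Hoxa11 (14.6 and 8.99 against 0.044 CPM). Mesonephros and intermediate mesoderm was higher in 9 of 12 genes, with 2 lower and 1 not past (9 and 2 adjusted over the list alone; adjusted p = 0.0177), with Wt1 at 5.35 ± 0.20, Osr1 at 4.37 ± 0.36 and Emx2 at 3.59 ± 0.24. Gonad and coelomic epithelium was higher in 4 of 8, with 4 not past (4 and 0 adjusted over the list alone; adjusted p = 0.0348), Gata4 by 5.82 ± 0.71 and Upk3b by 5.11 ± 0.47. Sympathoadrenal genes were higher in 4 of 9, with 2 lower and 3 not past (4 and 3 adjusted over the list alone; adjusted p = 0.0321, and 0.0651 with the block), with Hand2 at 5.61 ± 0.24. Dbh stood at 61.0 and 42.2 against 0.132 CPM (ratio 391, interval 134 to 1894).

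Simple epithelium was higher in 7 of 8 genes and lower in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0175, and 0.0513 with the block), Krt8 by 2.36 ± 0.20. Macrophage genes were higher in 8 of 12, with 4 not past (10 and 0 adjusted over the list alone; adjusted p = 0.019), F13a1 by 1.39 ± 0.24 and Cx3cr1 by 1.12 ± 0.26. Neural crest and glia was lower in 3 of 7, with 2 higher and 2 not past (2 and 3 adjusted over the list alone; adjusted p = 0.0119), Fabp7 by -4.20 ± 0.23. Imprinted growth genes were higher in 7 of 10, with 1 lower and 2 not past (7 and 1 adjusted over the list alone; adjusted p = 0.00759), Peg3 by 2.10 ± 0.11, H19 by 1.86 ± 0.14 and Igf2 by 1.48 ± 0.32. Notch pathway genes were lower in 5 of 8, with 1 higher and 2 not past (1 and 6 adjusted over the list alone; adjusted p = 0.0161), Hes5 by -4.67 ± 0.21. Haematopoietic stem and progenitor genes were higher in 7 of 18, with 2 lower and 9 not past (7 and 3 adjusted over the list alone; adjusted p = 0.248), among them Itga2b (1.64 ± 0.42) and Nfe2 (1.47 ± 0.31). Here the 10-library fit called 4779 genes, 2338 higher and 2441 lower, and 8491 (4006 higher and 4485 lower) with the round as a block. Over all 14 libraries edgeR called 0 (847 at an unadjusted p under 0.05), limma-voom 0, DESeq2 256, and edgeR with the replicate block 3844, 2275 higher and 1569 lower. On simulated counts of this comparison the 10-library fit recovered 77% of 2-fold and 100% of 4-fold changes, and 10.2% of its calls were unchanged genes. There too skin was simulated with the AGM spread.

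Whether the step from E9.5 to E10.5 differed between tissues was tested as the AGM change minus the skin change. Positive values mark genes that rose more, or fell less, in the AGM. Macrophage genes went opposite ways, with 9 of 12 higher at E10.5 in skin and 11 of 12 lower in the AGM. Of 9 early timing genes, 5 fell in skin and 3 rose in the AGM, with list calls that ended with the block in each tissue (adjusted p = 0.0959 and 0.0888 by fry). Lin28a differed by 4.15 ± 0.40 (edgeR adjusted p = 0.00246), Trim71 by 2.38 ± 0.21, Lin28b by 2.44 ± 0.31 and Sall4 by 1.87 ± 0.28. Early timing genes differed upward in 5 of 9, with 4 not past (7 and 0 adjusted over the list alone; fry adjusted p = 0.0175, and 0.0559 with the block). Olig2, falling from 51.7 to 20.7 CPM in skin, differed by 6.02 ± 0.32, and Sox1 by 4.05 ± 0.41. The neuronal genes Dcx and Nefl differed by -3.47 ± 0.41 and -3.41 ± 0.28. The neural tube list as a whole had 3 upward, 7 downward and 3 not past (4 and 8 adjusted over the list alone; adjusted p = 0.0345, downward, and 0.0563 with the block).

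Simple epithelium differed upward in 7 of 8 genes, with 1 not past (7 and 0 adjusted over the list alone; adjusted p = 0.0177), with Krt18 at 2.44 ± 0.22, Cldn6 at 2.01 ± 0.22 and Epcam at 1.72 ± 0.29. Macrophage genes differed downward in 11 of 12, with 1 not past (0 and 12 adjusted over the list alone; adjusted p = 0.0073), F13a1 by -4.73 ± 0.49. Hair placode genes differed upward in 3 of 11, with 8 not past (5 and 0 adjusted over the list alone; adjusted p = 0.0148), Lhx2 by 2.17 ± 0.30 and Lef1 by 0.90 ± 0.22. Neural crest and glia differed downward in 2 of 7, Fabp7 (-2.43 ± 0.35) and Ngfr (-1.30 ± 0.21), with 5 not past (0 and 2 adjusted over the list alone; adjusted p = 0.0128). The melanoblast list differed downward in 2 of 7, with 5 not past (0 and 3 adjusted over the list alone; adjusted p = 0.00156), Ednrb by -1.57 ± 0.17. Cell cycle genes differed upward in 2 of 20, Mcm7 (0.66 ± 0.15) and Ccne1 (0.85 ± 0.20), with 18 not past (3 and 0 adjusted over the list alone; adjusted p = 0.0321, and 0.0752 with the block). In the retinoic acid pathway Cyp26c1, which degrades retinoic acid, differed by 4.63 ± 0.51 and 7 of 8 genes did not pass (1 and 0 adjusted over the list alone; adjusted p = 0.0274, and 0.0871 with the block). Hand2 differed by 4.82 ± 0.29. The test called 1530 genes, 524 upward and 1006 downward, in the 10-library fit, and 5137 (2462 upward and 2675 downward) with the round as a block. The count was 945, 930 and 959 without the first-round AGM library labelled E9.5, the first-round one labelled E10.5 and the second-round one labelled E10.5. With all 14 libraries fitted, edgeR called 0 with or without the block (62 at an unadjusted p under 0.05 without it), limma-voom 0 and DESeq2 0. If the AGM labels E9.5 and E11.5 are exchanged, the AGM step runs back in age from E11.5 to E10.5. Opposite directions could then follow from age alone, which was not tested.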

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

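The difference between the tissues' changes was planned before the data were examined, while its 10-library fit and the picking of these genes and lists came only after the result was seen. The results below drew attention because the change from E9.5 to E10.5 differed between AGM and skin, with the edgeR or fry adjusted p under 0.05 in that fit. If the E9.5 and E11.5 AGM labels are exchanged, the AGM step runs from E11.5 back to E10.5 and these differences mix age with tissue. Of 89 selected genes that fell steadily with age in skin, 86.5% go with that reading. For Ambp, Barx1 and Robo3 the AGM rounds moved in opposite directions. The sign that their rounds share therefore comes from the single skin libraries. Nepn (adjusted p = 0.00803) went from 19.1 to 0 CPM in skin and from 0.0677 and 0.123 to 0.122 and 2.21 CPM in the AGM. Ambp (adjusted p = 0.0109) went from 5.27 to 0 CPM in skin and from 0.237 and 0.164 to 0.122 and 0.349 CPM in the AGM. Tcf21 (adjusted p = 0.00371) went from 4.52 to 0 CPM in skin and from 36.8 and 28.1 to 14 and 13.5 CPM in the AGM. Gpr50 (adjusted p = 0.0138) went from 7.93 to 0.264 CPM in skin and from 0.339 and 0.164 to 0.897 and 5.42 CPM in the AGM. Barx1 (adjusted p = 0.0118) went from 13.4 to 0.044 CPM in skin and from 2.47 and 3.41 to 4.57 and 1.28 CPM in the AGM.

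On the downward side, edgeR gave Ppp1r1c an adjusted p of 0.00556 (0 to 5.55 CPM in skin, 0.102 and 0.164 to 0.0408 and 0.0775 CPM in the AGM). The Ctss value was 0.00177 after adjustment (0 to 1.58 CPM in skin, 8.23 and 7.31 to 1.35 and 1.28 CPM in the AGM). Slc17a6 had 0.00375 (0.0502 to 5.37 CPM in skin, 1.02 and 0.657 to 0.449 and 0.465 CPM in the AGM). Robo3 had 0.00743 (1.76 to 78.4 CPM in skin, 2.10 and 0.247 to 0.286 and 0.387 CPM in the AGM). C1qc had 0.00305 (0.0502 to 2.38 CPM in skin, 11.9 and 12.0 to 4.81 and 3.60 CPM in the AGM).

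Among the lists, fry adjusted p-values were 0.0177 for simple epithelium, 0.0148 for hair placode, 0.0175 for early embryonic timing, 0.0321 for cell cycle and 0.0274 for the retinoic acid pathway, all upward. Downward they were 0.0345 for neural tube and neurons, 0.0128 for neural crest and glia, 0.00156 for melanoblasts and 0.0073 for macrophages. With the AGM round as a block the value was 0.0559 for early embryonic timing, 0.0752 for cell cycle, 0.0871 for the retinoic acid pathway and 0.0563 for neural tube and neurons, none of them under the threshold. Markers named for hair placode or melanoblasts are also made by other cells at these ages, so each list is given by its measured direction only.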

How the results depend on the processing

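The counts of called genes, the list tests and the named genes were recomputed with other settings, and the cause was not tested for any value that moved. Settings chosen before the data were examined kept 0 calls over all 14 libraries except in these cases, with comparisons in the order skin E10.5 against E9.5, E12.5 against E10.5, E14.5 against E12.5, E14.5 against E9.5, AGM E10.5 against E9.5, E11.5 against E10.5, AGM against skin at E9.5 and at E10.5, and the difference between tissues. DESeq2 called 2, 7, 12, 46, 5, 74, 308, 256 and 0 genes. The replicate block, which pairs libraries of a project or round, gave 0, 2, 10, 34, 0, 50, 4321, 3844 and 0, and 32 list tests (30 up and 2 down). Only the AGM libraries gave 457 and 4791 for the AGM ages, while only the skin libraries, or only the libraries of E9.5 and E10.5, gave 0. Leaving out any 1 library of the compared groups kept 0 genes in each comparison, and without the second-project skin library of E14.5 fry called 10 list tests. Chosen after seeing the data, the fit without second-project skin gave 1282, 6003, 5488, 9294, 488, 4809, 6759, 4779 and 1530 genes, and with the 6-library fit 159 list tests (95 up and 64 down). Without the second-round AGM libraries every count stayed at 0, as over all 14 libraries, which says nothing on the smaller fits. Within the smaller fits, DESeq2 moved AGM E10.5 against E9.5 from 457 to 931. Without the low-count filter skin E10.5 against E9.5 gave 2151, AGM E10.5 against E9.5 gave 1769 and the difference between tissues 2651. The block on the AGM round gave 3872, 9568, 9023, 11915, 4237, 8491, 10234, 8491 and 5137, in the same order. It changed the call of none of the named genes, and gave 148 list tests (82 up and 66 down) in place of 159, with some lists called only without the block and others only with it. These list tests, rerun with settings chosen after seeing the data, numbered 157 with median-of-ratios size factors, 141 without the low-count filter and 57 to 105 with 1 AGM library left out, lowest without the second-round library labelled E10.5 (57) and the first-round one (58). With the block the share of higher calls was 59.3% instead of 72.2% for skin E10.5 against E9.5, 50.3% instead of 33.7% for AGM E10.5 against E9.5 and 47.9% instead of 34.2% for the difference between tissues. A minimum change of 1 log2 (glmTreat) left 246, 1699, 1820, 3711, 1 (Olig2, named after its value was seen), 822, 1479, 1291 and 327. Leaving out 1 AGM library at a time gave 1084 to 1299, 5387 to 5854, 4971 to 5355, 8825 to 9148, 1 to 477, 2794 to 4566, 4685 to 6457, 3195 to 4675 and 930 to 1561. For AGM E10.5 against E9.5 the lowest count, 1 (Olig2), came without the second-round library labelled E10.5, with 24 without the first-round library labelled E9.5 and 104 without the first-round library labelled E10.5. Of the 306 named gene results, 294 kept their sign in the fit of all 14 libraries but were not called. That fit called no gene, so the loss of these calls was fixed in advance. Another 2 took the opposite sign there, Clca3a1 (log2 change -0.14) and Ctss (-3.61) in AGM against skin at E9.5. The rest were removed by the low-count filter of that fit and not tested in it. Within the smaller fits, 1 call was lost with DESeq2 and 12 with limma-voom, each with its sign kept. The largest number of calls lost by leaving out 1 library was 27, for the second-round AGM library labelled E10.5. Sizes of the changes were not compared between settings.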

Other observations

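For the AGM ages, the label exchange was stated before its values were seen, while the tests of dissection and extra tissue were chosen only after the result was seen. In both rounds the libraries labelled E11.5 held more tailbud and early-timing RNA than those labelled E9.5. The second-round ages were carried over from the first-round sample numbers, so that round is no independent check of the labels. Falling genes were those lower at each step of first-project skin, at least 4-fold from E9.5 to E14.5, with 10 CPM or more at E9.5. Rising genes met the same rule in the other direction, with 10 CPM or more at E14.5. Members of the neural tube, neural crest and tailbud lists were left out, but other genes of those tissues were not. Of the falling genes, 86.5% (77 of 89) were higher in the AGM libraries labelled E11.5 in both rounds. Of the rising genes, 463 of 533 were lower in both. A candidate explanation is that the E9.5 and E11.5 labels were exchanged. A caudal dissection of the libraries labelled E9.5 would raise tailbud genes in them. The tailbud list's median was instead at least 2.94 log2 higher in those labelled E11.5, which restates the pattern. If the labels are exchanged, the caudal dissection falls on the libraries labelled E11.5, and the value does not speak against it there. Extra tailbud tissue of E11.5 embryos is argued against by the Hbb-bh1 share, at least 12.0 percentage points higher in the libraries labelled E11.5. That reading assumes that the share falls up to E11.5, an age without a skin library. Whether tissue or age differences between dissections may contribute stays open as untested.

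For second-project skin, every test was chosen only after the result was seen. Libraries of the same age differed between projects, with Spp1 and Mmp3 high and haemoglobin counts near 0. Lower depth is argued against by the globin counts, at most 0.00635% of those that first-project shares would give, and an exchange of libraries by the highest correlation with any of the other 10 libraries, 0.788 against a lowest of 0.863 among those 10. Those values cover 19107 genes at 1 CPM or more in any library, and over the genes of the heat map they are 0.719 and 0.819. A list of 24 culture genes lay at percentile 100.0 of 10000 random lists at each age, but it was chosen after these values were seen and decides nothing. Whether cells grown in culture, a treatment or another tissue source may stand behind the pattern stays open, and the design names no biological difference between the projects to test.

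For the mitochondrial genes, the test of shared reads was stated before its value was seen and the test of total mitochondrial RNA only after the result was seen. mt-Co2 had 0 CPM in first-project skin, 0.901 and 3.63 CPM in the AGM rounds and 34.8 CPM in second-project skin, with mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l also near 0 in the first project. Less mitochondrial RNA in these libraries is argued against by the other mitochondrial protein genes, whose median in first-project skin was 63.7% of that in second-project skin over the 7 at 1 CPM or more and 45.5% over all 9 with mt-Nd3 and mt-Nd4l. Loss of reads shared with near-identical copies may explain mt-Co2, mt-Co3, mt-Atp6, mt-Nd4l and mt-Nd3, which had 0%, 0.136%, 0.475%, 1.21% and 2.01% of 50-base words of their own, but not mt-Atp8 at 100.0%. Only annotated transcripts were searched, so copies outside them stay open.

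In second-project skin, Spp1 had the highest values, and mt-Co1 (8312 to 11134 CPM) and Eef1a1 (6864 to 8650.4 CPM) were also among the highest. Matrix genes went both ways between projects, since Col1a1 ran from 1610.2 to 2647 CPM (118 to 10467 CPM in the first project) and Col3a1 from 2682 to 3735 CPM (499.8 to 10693 CPM). Tenascin, Tnc, ran from 6506 to 12384 CPM (3.21 to 357 CPM in the first project), and fibronectin, Fn1, from 7476 to 9096 CPM. The lysosomal protease gene Ctsl ran from 7223 to 9943 CPM (120 to 215 CPM), and Timp1, an inhibitor of matrix proteases, from 888 to 1487 CPM (3.83 to 7.92 CPM). The chemokine gene Ccl2 lay between 790 and 1160 CPM and the prostaglandin enzyme gene Ptgs2 between 418 and 1460 CPM. Grem1, a BMP antagonist, ran from 762 to 1258 CPM (12.2 to 47.4 CPM). Fos lay at 11.6, 14.3, 201 and 202 CPM in the single libraries from E9.5 to E14.5, with no test of that difference.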
